A study of Homo sapiens with 12 samples.

How the data were processed

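Gene expression was measured by RNA sequencing in primary human articular chondrocytes, the cells that make and maintain the matrix of joint cartilage, from 4 independent donors at 3 passages in culture. The passage number (P0, P3 or P6) counts how often the cultured cells had been replated. There were 12 libraries, 1 per donor and passage, so the donor cultures are the replicates (n = 4 per passage). Per the labels, RNA was extracted with the Zymo Direct-zol kit and sequenced as paired-end reads of 150 bp on an Illumina HiSeq X. The labels give the molecule as polyA RNA and the library preparation as depletion of ribosomal RNA, so it is not settled which RNA was selected. A library that keeps RNA without a polyA tail also holds unspliced transcripts and small structural RNAs, and the levels of such genes depend on that choice. No sequencing or library batch was given in the sources used here.

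The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2, DESeq2 and the GRCh38 genome. The authors deposited 1 table of TPM for 57500 genes, read counts divided by transcript length and scaled so that every library sums to 1000000. The annotation release and the step that turned counts into TPM are not given in the sources used here, nor is the strand setting of the counting. Reads from overlapping or antisense genes, and reads shared between near-identical genes, can therefore not be assigned with certainty. TPM are shares: a rise of a few abundant genes lowers all others, and a value carries no record of how many reads it rests on.

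Depth was estimated from the values. Multiplied by the exon length of GENCODE release 29, the low values of a library (under 20 reads) were whole multiples of 1 number, within 0.03 reads, for 95.92 to 96.53% of the genes. This gave an estimated 23300000 to 36550000 assigned reads per library. Whether these were single reads or read pairs is unknown. At these depths a protein-coding gene at about 1 TPM rested on a median of 20 to 38 reads, depending on the library, and one at about 10 TPM on 312 to 523. The method was chosen after the data were seen, and no result of the main tests uses it. Of the 57500 genes, 56898 (98.95%) were matched to GENCODE release 29 by identifier; gene coordinates are from that annotation (GRCh38).

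XIST, TSIX, Y-linked genes and genes whose level is often set by a donor's germline alleles (such as the HLA genes and GSTM1) were taken out before any test, 556 genes in all, and are not reported. Genes with at least 1 TPM in at least 4 libraries were kept, which left 18041. Expression was analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (a linear model of passage over all 12 libraries, moderated two-sided tests with an intensity trend). Adjusted p is the Benjamini-Hochberg value over all genes tested, with a threshold of 0.05. A fold change is on the log2(TPM + 1) scale, which understates the change of genes near 1 TPM. The comparisons were P3 against P0, P6 against P0, P6 against P3, and the early change (P3 minus P0) minus the late change (P6 minus P3). The test, the filter, the 31 gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where stated.

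The 31 gene lists covered cartilage and fibrous matrix, transcription factors, signalling, stress and metabolic pathways, and markers of other cell types that cartilage preparations can hold. All list members were found in the table, 9 of them under another symbol than the one listed. Lists with at least 3 measured members (29 of 31) were tested with limma's camera, with the inter-gene correlation preset to 0.01 and adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. A preset correlation takes members as nearly independent, so its p-values are too small where members vary together across donors.

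Named genes were the 12 largest rises and the 12 largest falls per comparison between passages (6 per direction for the early minus late change) among genes past the threshold, changed the same way in all 4 donors and with a mean of at least 10 TPM in the higher group. To these were added up to 4 members of each list past the threshold, and 8 genes always named (SOX9, SOX5, SOX6, COL2A1, ACAN, COL1A1, COL1A2, COL10A1). MKI67, TOP2A, COMP, CDKN1A, ACTA2, COL5A2, COL11A1, B3GAT3 and WNT11 lie outside that rule and were chosen after their values were seen.

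Donor numbers in the labels pair the libraries across passages. In each pair of passages, deviations from the passage mean of libraries of the same donor correlated at 0.23 to 0.48 across genes (mean 0.31), those of different donors at -0.29 to 0.15, and 24 of 24 best matches were of the same donor. The fit without a donor term was the main one, and the fit with the donor as a block is given where it changed a call or moved a count by over 1.5 times. The highest correlation between any pair of libraries was 0.978, so no library was a copy of another.

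Shares of the summed TPM were compared with exact two-sided permutation tests (4 against 4), whose smallest possible p is 0.0286, adjusted over 12 tests. Alternatives were other pseudocounts and filters, rescaling by the median of ratios, quantile normalisation, leaving out mitochondrially encoded genes, no intensity trend, only the passages compared, the donor block, and each donor and each library left out in turn. Limma's voom on the recovered reads was added after the data were seen. The main script was tested on simulated data with 18041 genes of which 200 were changed. Of changes of 1 and of 2 on the log2 scale it recovered 43% and 83% for P3 against P0 and 46% and 87% for P6 against P0, with 11 and 8 false calls. For the early minus late change it recovered 17% and 52%, with 7 false calls, and for P6 against P3, where no gene had been changed, it made 0 calls. The simulated genes and libraries were drawn independently, without differences between donors, so these rates need not hold for the real libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for all other steps.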

Results

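Chondrocytes lose their cartilage phenotype when they are passaged in culture, a process called dedifferentiation, and the series followed it in cells of 4 donors at P0, P3 and P6. The 12 libraries held an estimated 23300000 to 36550000 assigned reads, with means of 26200000 at P0, 27800000 at P3 and 30000000 at P6. The first principal component held 30.4% of the variance of the 18041 genes tested and placed every P0 library (scores -82.6 to -13.2) below every P3 library (-2 to 27.4) and every P6 library (16.9 to 30.7). P3 and P6 libraries overlapped along it, and the P0 libraries were the most widely spread (scores -82.6, -53.7, -13.2 and -17.9 for donors 1 to 4).

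**Figure D1:**
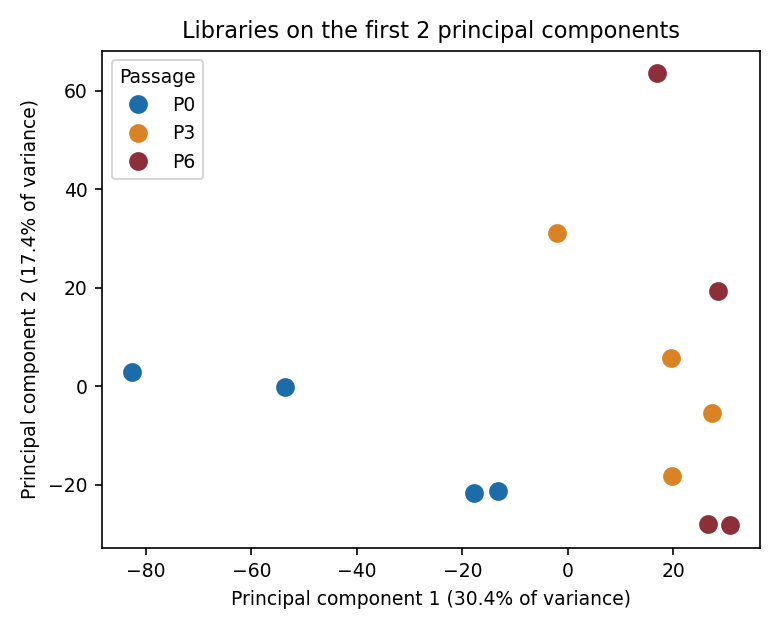
Each point is 1 library on the first 2 principal components of log2(TPM + 1), with the share of variance on each axis (30.4% and 17.4%) and colour for passage (n = 4 each). The 4 P0 libraries lie at -82.6 to -13.2 on the first component, and all P3 and P6 libraries lie at -2 or above.

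The first comparison asks what changed between P0 and P3, where 5 collagen genes of cartilage fell. COL2A1, the main collagen of hyaline cartilage (ENSG00000139219, chr12:47972965-48004554, GRCh38), went from 3320 ± 4960 TPM at P0 to 38.9 ± 23.0 at P3 (SD, n = 4), 46.0-fold lower on the log2(TPM + 1) scale (log2 change -5.52, SE 0.89, limma adjusted p = 0.0245). It was lower in 4 of 4 donors. On that scale COL11A2 fell by 5.29 and COL9A3 fell by 4.29, from 400 ± 619 to 3.54 ± 1.73 TPM and from 389 ± 435 to 14.5 ± 9.02 TPM. COL11A1 did not pass (log2 change -2.30, adjusted p = 0.0766). COL9A2, COL9A1, the cartilage proteoglycan gene SNORC and CNMD, which encodes the anti-angiogenic cartilage protein chondromodulin, had log2 changes of -4.06 to -3.79. The sizes depended on single libraries, and the P0 mean of COL2A1 rested on donor 1, at 10700 TPM against 520 to 1000 in the other donors. Without the P0 library of donor 1 the changes were -4.59 for COL2A1, -4.29 for COL11A2, -3.64 for COL9A3, -3.46 for SNORC, -3.15 for COL9A2 and -2.98 for COL9A1. Without donor 1 they were -4.89 for COL2A1, -4.43 for COL11A2, -3.25 for COL9A2, -3.21 for CNMD and -3.03 for COL9A1, and without donor 3 -6.27 for COL2A1, -6.03 for COL11A2 and -4.96 for COL9A3. SOX9, the transcription factor that drives cartilage genes (ENSG00000125398, chr17:72121020-72126420), fell 4.54-fold, from 155 ± 66.4 to 32.5 ± 9.18 TPM (log2 change -2.18, SE 0.30, adjusted p = 0.0140). Its partner SOX5 (chr12:23529500-24562544) fell 3.66-fold, from 35.9 ± 18.8 to 8.26 ± 1.17 TPM (log2 change -1.87, SE 0.27, adjusted p = 0.0146).

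ACAN, which encodes the large cartilage proteoglycan aggrecan (ENSG00000157766, chr15:88803442-88875354), did not pass the test. Its mean was 1280 ± 1490 TPM at P0 and 569 ± 220 at P3, lower in 3 of 4 donors (log2 change -0.63, SE 0.59, adjusted p = 0.620). The P0 mean rested on donor 1, at 3510 TPM against 422 to 707 in the other donors, and without that library the log2 change was 0.06. COL1A1, the fibrous collagen gene often used as a marker of dedifferentiation (ENSG00000108821, chr17:50183289-50201632), was at 2630 ± 1700 TPM at P0 and 8270 ± 2690 at P3, higher in 4 of 4 donors. Its log2 change of 1.85 (SE 0.53) had an adjusted p of 0.124, and of 0.0325 with the donor as a block. COL1A2 (chr7:94394561-94431232) was at 2890 ± 1060 and 5780 ± 660 TPM, higher in 4 of 4 donors (log2 change 1.08, SE 0.27, adjusted p = 0.0897, and 0.0347 with the block). SOX6 (chr11:15966449-16739591) was at 5.65 ± 3.16 and 2.06 ± 0.684 TPM (log2 change -1.04, SE 0.29, adjusted p = 0.113). COL10A1, a marker of hypertrophic chondrocytes, reached 1 TPM in 2 libraries, with a highest value of 16.7 TPM, and was not tested.

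**Figure D2:**
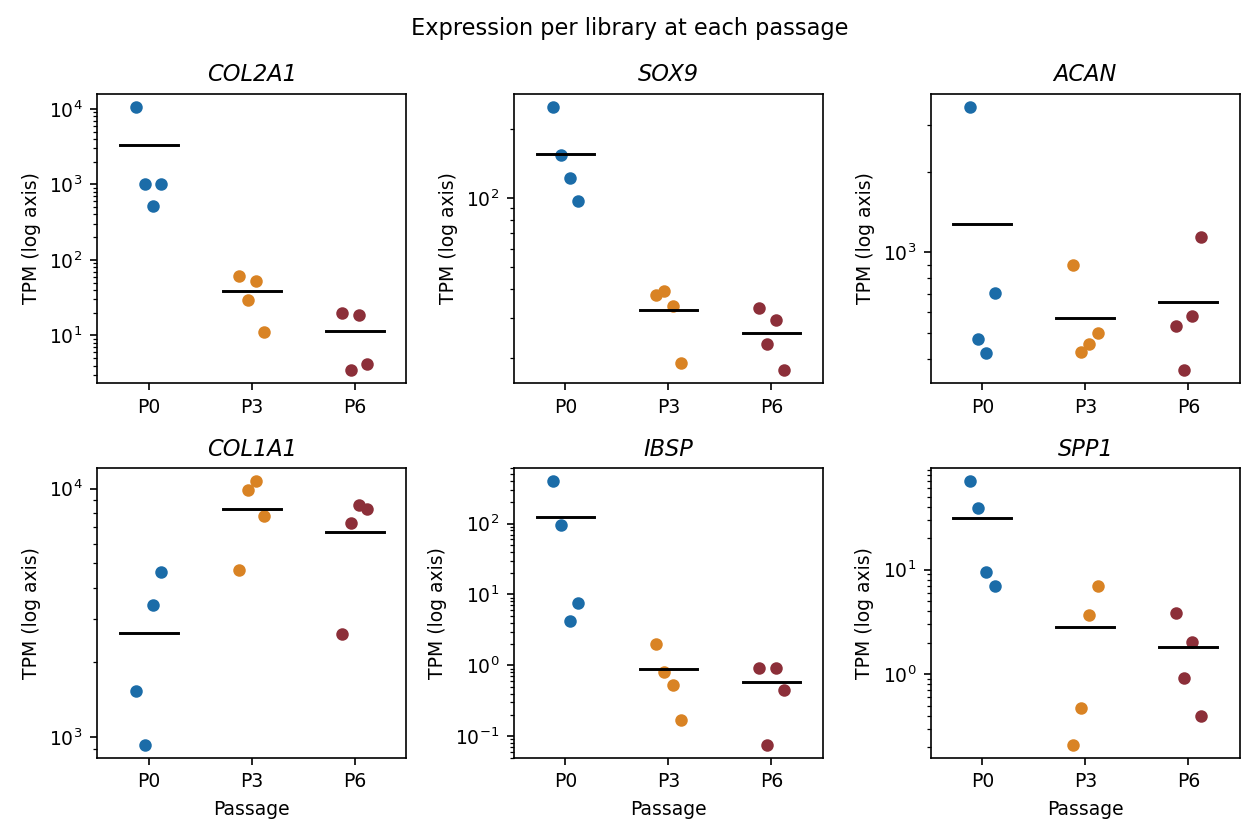
Each point is the TPM of 1 library on a log axis whose range differs between panels, by passage (n = 4 donors each), and each line is the passage mean. COL2A1 lies at 520 TPM or above in all P0 libraries and at 62.1 or below in all others, whereas the ACAN values of the 3 passages overlap.

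In all, 70 genes changed between P0 and P3, of which 8 rose and 62 fell, and 57 of them changed at least 2-fold (8 up, 49 down). The largest rises were those of MSC, a transcriptional repressor of the basic helix-loop-helix family, from 2.74 ± 2.32 to 15.0 ± 3.58 TPM, and of FLNC, an actin crosslinking filamin, from 6.75 ± 1.48 to 35.0 ± 7.50 TPM (log2 changes 2.28 and 2.21). CARD10, a signalling scaffold upstream of NF-kB, and FZD2, a WNT receptor, rose by 2.05 and 1.46. Outside the cartilage collagens, the largest falls included PLA2G2A, a secreted phospholipase, which fell 15.3-fold from 695 ± 618 TPM. The calcium-binding gene S100A1 fell 12.8-fold, ITIH6 12.1-fold, the secreted cartilage protein gene MIA 9-fold and B3GNT7 7.98-fold. ENPP1, which makes the mineralization inhibitor pyrophosphate, fell from 181 ± 74.9 to 28.3 ± 10.1 TPM, the growth factor receptor gene FGFR2 from 103 ± 39.6 to 30.7 ± 5.34, and GPX3, a secreted glutathione peroxidase, from 923 ± 484 to 169 ± 48.4. The E3 ubiquitin ligase gene WWP2 fell from 116 ± 72.0 to 28.1 ± 1.91 TPM.

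The count of 70 became 861 (244 rose, 617 fell) with the donor as a block, and all 70 were among these. It depended on single libraries, at 42, 4, 229 and 223 without the P0 library of donors 1 to 4, 43, 5, 11 and 4 without their P3 library and 58, 1, 9 and 13 without the whole donor. Each of the 22 calls named here was lost in at least 1 of 16 leave-one-out fits, those of MSC, CARD10 and WWP2 in 13. Of the calls 11.4% rose in the TPM as deposited, 33.9% after median-of-ratios rescaling and 32.1% after quantile normalisation. The median change of all genes tested was -0.11 as deposited and 0.01 after median-of-ratios rescaling, against -0.08 and 0.01 for P6 against P0. The early minus late change gave -0.12 and 0.02.

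By gene list, 8 of 27 measured cartilage matrix genes fell between P0 and P3 and 0 rose (22 fell adjusted over the list alone, 16 with the donor block). The mean log2(TPM + 1) of the list at P0 was 8.72, 7.33, 6.34 and 6.40 in donors 1 to 4, and that of the osteoblast markers 4.41, 3.96, 3.16 and 3.18, so donors 1 and 2 were highest in both. The cartilage list was lower than the other genes by camera, with a median log2 change of -2.61 (adjusted p = 3.76e-16, and adjusted p = 0.19 with an estimated correlation). In the list of chondrogenic and skeletal transcription factors, SOX9, SOX5 and WWP2, a ubiquitin ligase gene held in the list, fell among 25 genes (13 adjusted over the list alone, 7 with the donor block), and camera placed the list lower (adjusted p = 6.49e-06, and adjusted p = 0.19 with an estimated correlation). Of 12 hypertrophy and mineralization genes, ENPP1 fell (7 adjusted over the list alone, 6 with the block; camera adjusted p = 0.000506, and adjusted p = 0.19 with an estimated correlation). Camera placed the fibrous matrix list higher, with a median log2 change of 0.45 (adjusted p = 6.26e-06, and adjusted p = 0.19 with an estimated correlation). None of its 28 members passed over all genes, and 6 rose and 2 fell adjusted over the list alone (5 and 2 with the block over all genes). The 22 contractile and SRF target genes were higher by camera, with a median of 0.39 (adjusted p = 2.35e-06, and adjusted p = 0.531 with an estimated correlation), with 0 single calls over all genes and adjusted over the list alone, and 5 that rose with the block. Among these, ACTA2, the smooth muscle actin gene, was at 77.8 ± 72.6 and 275 ± 196 TPM, higher in 4 of 4 donors (adjusted p = 0.263, and 0.00708 with the block).

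With no single gene past the threshold without the block, over all genes or adjusted over the list alone, camera also placed higher the NF-kB and inflammatory list (25 genes, median 0.41, adjusted p = 3.94e-05, and adjusted p = 0.19 with an estimated correlation) and the senescence and p53 target list (20 genes, median 0.28, adjusted p = 0.0017, and adjusted p = 0.512 with an estimated correlation). The same held for the 13 mitochondrially encoded genes (median 0.35, adjusted p = 6.26e-06, and adjusted p = 0.277 with an estimated correlation) and the 34 ribosomal protein genes (median 0.19, adjusted p = 7.21e-07, and adjusted p = 0.591 with an estimated correlation). The 35 cell cycle genes were placed lower (median -0.56, 35 of 35 lower, adjusted p = 0.00102, and adjusted p = 0.683 with an estimated correlation), as were the 24 hypoxia and glycolysis genes (median -0.46, adjusted p = 0.0108, and adjusted p = 0.591 with an estimated correlation), of which 7 fell adjusted over the list alone and 0 over all genes. With the block 3 NF-kB genes and 1 senescence gene rose, and 1 cell cycle gene and 5 hypoxia genes fell. MKI67, a gene of dividing cells, was at 26.7 ± 23.2 TPM at P0 and 14.6 ± 10 at P3 (adjusted p = 0.560). The cell cycle call ended without the P0 library of donor 1 (0.277), the P3 library of donor 2 (0.114), donor 2 (0.0572) or donor 4 (0.0519), and the senescence call without the P0 library of donor 1 (0.0592). The mitochondrial call ended after quantile normalisation (0.202). The hypoxia call ended without the P0 library of donor 3 (0.0997), the P3 library of donor 2 (0.0685), donor 2 (0.17) or donor 3 (0.133).

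The other lists did not pass camera for P3 against P0. FZD2 rose among 20 WNT pathway genes (4 rose and 5 fell adjusted over the list alone; adjusted p = 0.574), FGFR2 fell among 22 IGF and FGF genes (2 and 5; adjusted p = 0.816), and GPX3 fell among 20 metallothionein and antioxidant genes (0 and 2; adjusted p = 0.789). The endoplasmic reticulum stress list had an adjusted p of 0.0804 (0.0154, lower, with the donor block, and adjusted p = 0.592 with the block and an estimated correlation; 5 of 20 fell adjusted over the list alone) and the synovial fibroblast marker list one of 0.0704 (0.0231, higher, with the block, and adjusted p = 0.413 with the block and an estimated correlation; 2 of 12 rose and 1 fell adjusted over the list alone). Values were 0.0804 for proteoglycan synthesis (6 fell adjusted over the list alone), 0.174 for mesenchymal transition factors, 0.225 for AP-1 and immediate early genes, 0.731 for YAP and TEAD targets (1 fell adjusted over the list alone) and 0.574 for matrix proteinases (1 rose and 3 fell). They were 0.424 for the interferon response, 0.816 for the TGF-beta and BMP pathway (5 fell), 0.789 for cholesterol biosynthesis and 0.954 for replication-dependent histones (1 rose). With the donor block the genes that rose and fell were 2 and 2 for the WNT list, 1 and 3 for IGF and FGF, 5 and 3 for antioxidant genes, 0 and 5 for endoplasmic reticulum stress and 3 and 0 for synovial markers. They were 0 and 2 for proteoglycan synthesis, 1 and 2 for mesenchymal transition factors, 0 and 1 for AP-1, 0 and 2 for YAP, 1 and 2 for proteinases, 1 and 0 for interferon and 0 and 4 for TGF-beta. For the WNT, antioxidant, YAP, interferon, TGF-beta, adipocyte marker and histone lists the median was below 0, and for matrix proteinases the mean, while camera, which sets members against all other genes, put the list higher. The sign of the median of the YAP, matrix proteinase, interferon, TGF-beta and adipocyte lists changed with the scaling.

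Between P0 and P6 the same cartilage collagen genes fell, and a set of genes at low levels at P0 rose. COL2A1 was at 11.4 ± 8.83 TPM at P6, 157-fold below P0 (log2 change -7.30, SE 0.89, adjusted p = 0.00184). PLA2G2A, COL9A3 and COL11A2 were 77.6-fold, 73.7-fold and 54.8-fold lower (log2 changes -6.28, -6.20 and -5.77). Without the P0 library of donor 1 the log2 change was -6.36 for COL2A1, -5.55 for COL9A3 and -4.78 for COL11A2, and without donor 1 it was -4.93 for COL11A2. Without donor 3 it was -8.15 for COL2A1, -6.93 for PLA2G2A and -6.49 for COL11A2. The chemokine gene CXCL12 (ENSG00000107562, chr10:44370165-44386493) rose 15.1-fold, from 3.04 ± 1.75 to 66.0 ± 49.8 TPM (log2 change 3.92, SE 0.54, adjusted p = 0.00331), and MSC rose 10.8-fold to 36.1 ± 15.3 TPM. SOX9 was 5.61-fold lower than at P0 (25.8 ± 6.75 TPM, adjusted p = 0.00184), SOX5 6.37-fold (4.31 ± 0.449 TPM, adjusted p = 0.000695) and SOX6 2.60-fold (1.42 ± 0.478 TPM, adjusted p = 0.0222).

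Among the other large rises from P0 to P6, KRTAP1-5, a keratin-associated protein gene, rose 11.1-fold to 29.7 ± 12.4 TPM. CCBE1, a secreted factor of lymphatic development, rose 10.7-fold to 68.5 ± 18.6, SECTM1 10.3-fold to 46.7 ± 34.9 and the small heat shock gene HSPB7 9.14-fold to 235 ± 124. The chemokine gene CXCL6 rose 9.13-fold, MFAP5, which encodes a microfibril protein, 8.30-fold and the potassium channel gene KCNK2 8.19-fold. FLNC rose 7.67-fold to 58.6 ± 11.9 TPM (adjusted p = 7.8e-05), the ubiquitin ligase gene HECW2 7.63-fold and PTX3, a secreted pentraxin, 7.28-fold, from 161 ± 135 to 824 ± 234 TPM. Among the falls, the proteinase gene MMP3 was 30.2-fold lower (973 ± 1260 to 13.9 ± 7.06 TPM), C2orf40 27.3-fold, the WNT antagonist gene FRZB 23.7-fold and S100A1 21.8-fold. CNMD and SNORC were 25.2-fold and 24.3-fold lower, and GDF10, a TGF-beta family gene, 21.0-fold. Several of these sizes depended on 1 library or donor. The log2 change of CCBE1 (3.42) was 2.78 without donor 1, and that of KCNK2 (3.03) was 3.71 without the P0 library of donor 3. That of PTX3 (2.86) was 2.25 without donor 1 and 2.15 without its P0 library. For MMP3 (-4.92) it was -4.27 without donor 2, -4.00 without its P0 library, -5.68 without donor 4 and -5.69 without its P0 library. For C2orf40 (-4.77) it was -4.12 without donor 1, -5.52 without donor 3, and -4.02, -4.15 and -5.62 without the P0 library of donor 1, 2 or 3. For GDF10 (-4.40) it was -3.43 without donor 1, -5.36 without donor 3, and -3.52 and -5.12 without their P0 libraries. SNORC (-4.60) gave -3.98 without donor 1 and -4.01 without its P0 library, and CNMD (-4.66) gave -4.07 without donor 1.

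ACAN was at 652 ± 337 TPM at P6, lower than at P0 in 2 of 4 donors and higher in 2 (log2 change -0.49, SE 0.59, adjusted p = 0.697). Its sign changed without donor 1 (0.25) or the P0 library of donor 1 (0.20). COL1A1 was at 6670 ± 2770 TPM (log2 change against P0 1.47, SE 0.53, adjusted p = 0.148, and 0.0450 with the block) and COL1A2 at 5480 ± 549 (1.00, SE 0.27, adjusted p = 0.0615, and 0.0277 with the block), both higher in 4 of 4 donors. COMP, a glycoprotein of cartilage and tendon, was at 4980 ± 2340 TPM at P0, 2390 ± 1630 at P3 and 1810 ± 1440 at P6 (adjusted p = 0.379 for P3 and 0.155 for P6 against P0).

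In all, 785 genes changed between P0 and P6 (233 rose, 552 fell), 444 of them at least 2-fold (143 up, 301 down), and 782 moved the same way in all 4 donors. With the donor as a block the count was 1885 (652 rose, 1233 fell), which held 783 of the 785. Of the calls, 29.7% rose, against 43.1% after median-of-ratios rescaling and 43.3% after quantile normalisation. Without the P0 library of donor 1 or 2 the count was 334 or 403, and without the P6 library of donor 1, 2 or 3 it was 474, 372 or 423; without donors 1 to 4 it was 325, 73, 254 and 329. Of the 76 calls named for this comparison, 19 held in all 16 leave-one-out fits, among them those of COL2A1, COL9A3, SOX9, SOX5, CXCL12, MSC and FLNC. Those of COL5A2, CXCL2 and MT-ND3 held in 1, of IGFBP3 and WNT11 in 2, of TEK in 3, of CD55, DKK1 and PDIA6 in 4 and of FGFBP2, TWIST2 and ZEB1 in 5.

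Of 27 cartilage matrix genes, 16 fell and 0 rose between P0 and P6 (22 fell adjusted over the list alone), and camera placed the list lower, with a median log2 change of -3.05 (adjusted p = 1.46e-18, and adjusted p = 0.168 with an estimated correlation). In the list of chondrogenic and skeletal transcription factors, 8 of 25 genes fell, WWP2 among them, and 1 rose (14 and 1 adjusted over the list alone and with the block), and the list was lower (camera adjusted p = 1.59e-06, and adjusted p = 0.168 with an estimated correlation). SOX8 fell 8.66-fold and NKX3-2 3.92-fold. Of 12 hypertrophy and mineralization genes, 6 fell (9 fell and 1 rose adjusted over the list alone), among them IBSP, a bone matrix protein gene, 23.3-fold, the collagenase gene MMP13 16.4-fold, ENPP1 11.8-fold and the mineralization inhibitor gene MGP 9.42-fold, from 2720 ± 1810 to 289 ± 218 TPM. The log2 change of MMP13 (-4.04) was -3.43 without the P0 library of donor 2, and that of MGP (-3.24) was -3.88 without donor 4. That of IBSP (-4.54) was -3.49, -3.90, -5.58 and -5.20 without donors 1 to 4, and -3.39, -5.47 and -5.23 without the P0 library of donor 1, 3 or 4. Camera placed that list lower (adjusted p = 7.34e-05, and adjusted p = 0.168 with an estimated correlation). Of 24 proteoglycan synthesis and sulfation genes, the 5 that passed fell: SLC26A2, a sulfate transporter, 2.37-fold, CHSY1 2.10-fold, CHST3 1.81-fold, DSE 1.58-fold and B3GAT3 1.33-fold (8 adjusted over the list alone; 8 fell and 1 rose with the block). The call of CHSY1 held in 16 of 16 leave-one-out fits, that of CHST3 in 2 and that of B3GAT3 in 0. The camera call of that list (adjusted p = 0.0265) was lost with the block (0.0778), and adjusted p = 0.585 with an estimated correlation. It ended too with voom and the block (0.0861) and without the P0 library of donor 1 (0.0556) or 4 (0.0555), the P6 library of donor 2 (0.0578), donor 1 (0.0823) or donor 3 (0.0653).

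The fibrous matrix list missed the camera threshold for P6 against P0 (adjusted p = 0.0535), with a median log2 change of 0.40 and 18 of 28 genes higher. Of these 28, 2 rose and 3 fell (7 and 4 adjusted over the list alone, 8 and 4 with the block): S100A4 rose 3.09-fold and COL14A1 2.46-fold, whereas the matrix glycoprotein gene TNC fell 5.13-fold, from 2660 ± 889 to 501 ± 96.1 TPM, LUM, a small leucine-rich proteoglycan gene, 3.21-fold and COL5A2 1.96-fold. Of the 22 contractile genes LMOD1, a smooth muscle actin nucleator, rose 5.89-fold (1 adjusted over the list alone, 8 with the block), and camera placed the list higher (median 0.37, adjusted p = 0.000325, and adjusted p = 0.619 with an estimated correlation). That call ended without the P6 library of donor 4 (0.0857). ACTA2 was at 388 ± 410 TPM, higher than at P0 in 4 of 4 donors (adjusted p = 0.179, and 0.00185 with the block). The proteinase genes MMP3, MMP13 and MMP1, the last 7.78-fold, fell among 20 matrix proteinases (2 rose and 4 fell adjusted over the list alone, 2 and 5 with the block), and the list did not pass (camera adjusted p = 0.94). The log2 change of LMOD1 (2.56) was 1.92 without the P0 library of donor 1, and that of MMP1 (-2.96) was -2.33 without donor 1 and -3.58 without the P6 library of donor 2.

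Camera placed the 35 cell cycle genes lower at P6 than at P0, with a median log2 change of -0.94 and 35 of 35 lower (adjusted p = 1.55e-07, and adjusted p = 0.585 with an estimated correlation). None of them passed alone over all genes or adjusted over the list alone, and 8 fell with the donor block. MKI67 was at 7.54 ± 4.17 TPM at P6 (adjusted p = 0.174) and TOP2A, a topoisomerase of dividing cells, at 63.2 ± 42.9 at P0 and 26.0 ± 10.2 at P6 (adjusted p = 0.203). The senescence and p53 target list was higher (median 0.38, camera adjusted p = 0.00131, and adjusted p = 0.425 with an estimated correlation), in which ZMAT3 rose 1.79-fold and GLB1, which encodes the lysosomal beta-galactosidase read out in senescence stains, fell 1.32-fold (3 rose and 1 fell adjusted over the list alone, 4 and 2 with the block). CDKN1A, the p21 cell cycle inhibitor gene, was at 557 ± 225 TPM at P0 and 964 ± 145 at P6, higher in 4 of 4 donors (adjusted p = 0.105, and 0.0236 with the block). The senescence list did not pass without donor 1 (0.12).

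Of 25 NF-kB and inflammatory genes, CXCL6 and CXCL2 rose (4 rose and 1 fell adjusted over the list alone, 6 and 2 with the block), and camera placed the list higher (median 0.51, adjusted p = 7.34e-05, and adjusted p = 0.168 with an estimated correlation). CXCL2 stayed low, at 0.922 ± 0.740 TPM at P0 and 3.31 ± 1.18 at P6. Of 24 hypoxia and glycolysis genes, the collagen prolyl hydroxylase gene P4HA1 fell 2.41-fold, PFKFB3 1.84-fold and PGK1 1.74-fold (10 fell and 1 rose adjusted over the list alone, 10 and 0 with the block), and the list was lower (camera adjusted p = 0.00131, and adjusted p = 0.425 with an estimated correlation). PDIA6 and XBP1 fell 1.92-fold and 1.44-fold among 20 endoplasmic reticulum stress genes (7 adjusted over the list alone, 10 with the block; camera adjusted p = 0.00575, lower, and adjusted p = 0.425 with an estimated correlation). Among the 13 mitochondrially encoded genes MT-ND3 rose 1.56-fold (1 adjusted over the list alone), and the list was higher (median 0.51, camera adjusted p = 4.13e-06, and adjusted p = 0.304 with an estimated correlation).

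Signalling genes moved in both directions between P0 and P6. In the WNT pathway, FZD2 rose 4.46-fold and the inhibitor gene DKK1 4.85-fold, whereas FZD8 fell 3.06-fold, NKD1 2.42-fold and WNT11 2.02-fold (4 of 20 rose and 6 fell adjusted over the list alone; camera adjusted p = 0.643). In the TGF-beta and BMP pathway GDF10, the BMP antagonist gene CHRDL2 (8.89-fold), BMP6 (6.94-fold) and BMP2 (5.27-fold) fell (5 of 28 adjusted over the list alone; camera adjusted p = 0.489). In the IGF and FGF axis FGF5 rose 6.18-fold, and FGFBP2, FGFR3 and FGFR2 fell 14.9-fold, 7.54-fold and 4.73-fold (3 of 22 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.94). IGFBP3, an IGF carrier among the most abundant transcripts, rose 4.00-fold to 30600 ± 6450 TPM, and TGFB2 fell 2.49-fold, in the YAP and TEAD target list (2 of 22 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.799). TWIST2 rose 3.46-fold and ZEB1 fell 1.77-fold among 14 mesenchymal transition factors (1 and 2 adjusted over the list alone; camera adjusted p = 0.433), and GPX3 fell 6.65-fold among 20 antioxidant genes (1 adjusted over the list alone; camera adjusted p = 0.799). The replication-dependent histone HIST3H2A rose 4.05-fold to 15.1 ± 9.06 TPM among 18 (1 adjusted over the list alone; camera adjusted p = 0.761). No member passed, over all genes or adjusted over the list alone, among AP-1 and immediate early genes without the block (camera adjusted p = 0.507), interferon response genes (0.0939), cholesterol biosynthesis genes (0.507) or ribosomal protein genes (0.0939). With the donor block 2 AP-1 genes and 1 cholesterol gene fell, and 3 interferon genes rose and 1 fell. The genes that rose and fell with the block were 5 and 5 for the WNT list, 2 and 6 for TGF-beta, 2 and 5 for IGF and FGF, 3 and 5 for YAP, 2 and 2 for mesenchymal transition factors and 5 and 4 for antioxidant genes. Camera put the matrix proteinase, WNT, IGF and histone lists higher although their medians lay below 0, and the sign of the proteinase, IGF and histone medians changed with the scaling. Without donor 1 the log2 change of FGFR3 (-2.91) was -2.02 and that of HIST3H2A (2.02) was 1.35, and without donor 3 that of DKK1 (2.28) was 2.99. That of CHRDL2 (-3.15) was -2.50, -2.36, -3.80 and -3.95 without donors 1 to 4 and -2.50 without the P0 library of donor 2. That of FGFBP2 (-3.89) was -2.85, -4.54 and -4.61 without donor 1, 3 or 4, and -3.10 and -4.68 without the P0 library of donor 1 or 4.

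**Figure D3:**
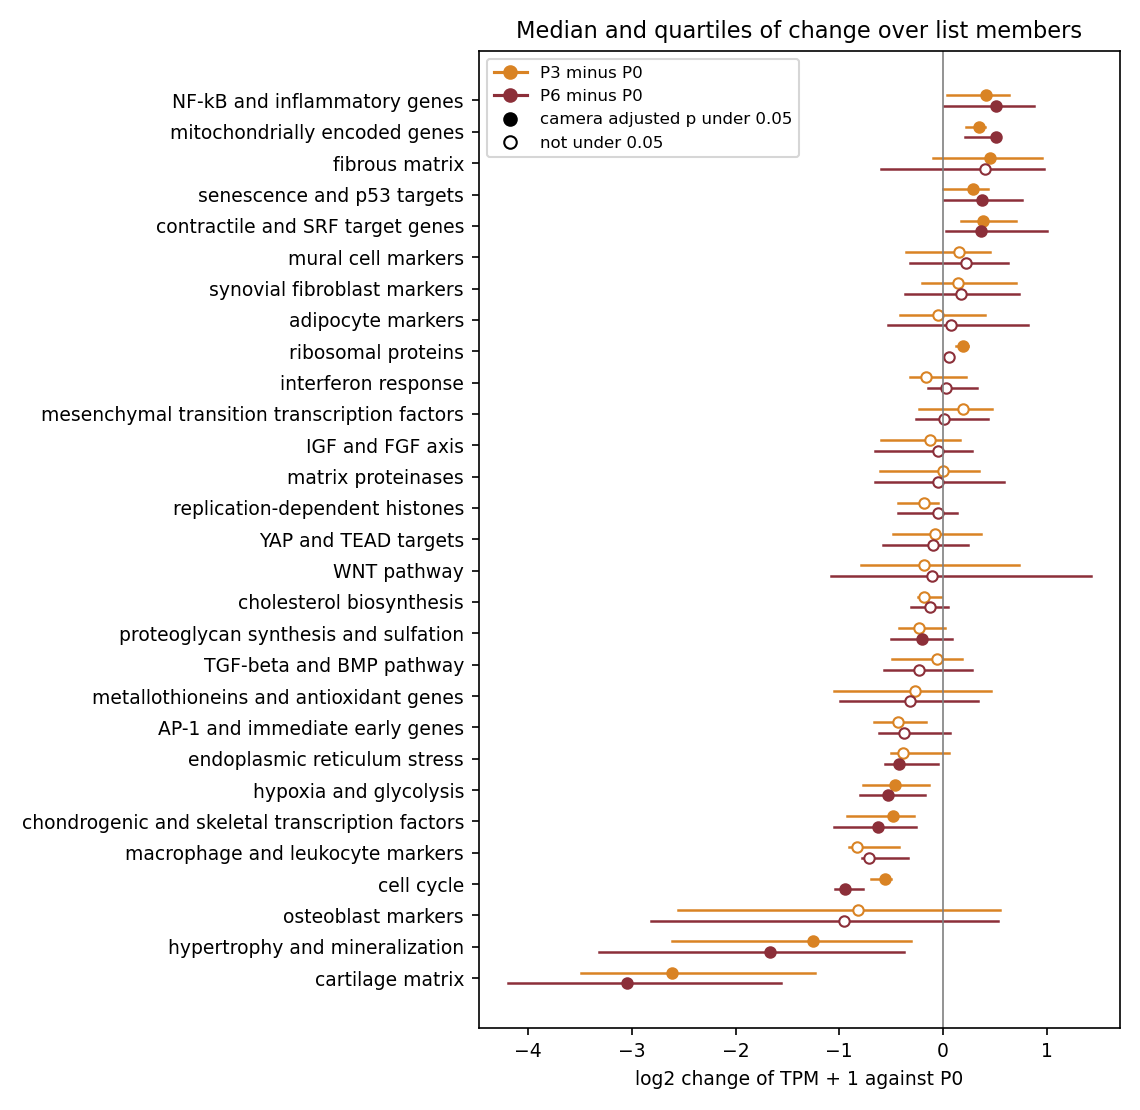
Points are the median and lines the quartiles, over the measured members of each of 29 gene lists, of the log2 change of TPM + 1 from P0 to P3 and to P6, and filled points have a camera adjusted p under 0.05 with a preset correlation (none does with an estimated one). The cartilage matrix list has the lowest medians, -2.61 and -3.05.

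Markers of other cell types were followed for cells that a cartilage preparation can carry over. The osteoblast marker list summed to 214 TPM at P0, 72.1 at P3 and 79.5 at P6, and at P0 it was led by 2 libraries: IBSP was at 395 and 94.6 TPM in donors 1 and 2 and at 4.16 and 7.50 in donors 3 and 4. SPP1 was at 70.3, 39, 9.49 and 7 TPM in donors 1 to 4. IBSP and SPP1 are also members of the hypertrophy and mineralization list. COL10A1, the marker of hypertrophic chondrocytes, was at 16.7, 4.67, 0.412 and 0.513 TPM in the P0 libraries of donors 1 to 4. These values do not tell carried-over osteoblasts from hypertrophic chondrocytes. The calls of IBSP and SPP1 held in 2 and 4 of 16 leave-one-out fits. From P0 to P6, IBSP, SPP1 (8.83-fold) and DLX5 (3.58-fold) fell among 6 measured osteoblast markers (3 adjusted over the list alone; camera adjusted p = 0.22, and 0.225 for P3 against P0 with 3 adjusted over the list alone). Fry placed the list lower at P3 (adjusted p = 0.0285, and 0.0689 with the block) and at P6 (0.0138, and 0.0392 with the block). The libraries of donors 1 and 2 were also the P0 libraries with the lowest scores on the first component. Of the macrophage and leukocyte markers, 4 of 16 were measured, and LAPTM5 fell 1.93-fold to 0.527 ± 0.393 TPM (1 adjusted over the list alone; camera adjusted p = 0.281, and 0.206 for P3). The highest value of any of the 16 was 43.9 TPM, of CD14. CXCL12 and MFAP5 rose and CD55 fell 1.43-fold among 12 measured synovial fibroblast markers (2 and 1 adjusted over the list alone; camera adjusted p = 0.137). Of 13 endothelial markers 2 passed the filter and the list was not tested, although TEK rose 1.85-fold to 2.27 ± 0.576 TPM. Mural cell markers (0.276 for P3 and 0.397 for P6 against P0) and adipocyte markers (0.669 and 0.542) did not pass camera, with 0 single calls over all genes and 1 adipocyte marker in each direction adjusted over the list alone at P6. With the donor block 1 mural marker rose and 1 fell against P0 at P3 and at P6, 2 leukocyte markers fell at each, and 2 osteoblast markers fell at P3. Erythroid markers reached at most 0.865 TPM and were not tested.

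From P3 to P6 no single gene passed the threshold. The smallest limma adjusted p was 0.0576, 781 genes had an unadjusted p under 0.05, and the counts were also 0 with the donor block (1274 unadjusted) and with voom on the recovered reads, and 4 with both. COL2A1 was at 38.9 ± 23.0 and 11.4 ± 8.83 TPM, lower in 4 of 4 donors (log2 change -1.77, SE 0.89, adjusted p = 1.0), and SOX5 at 8.26 ± 1.17 and 4.31 ± 0.449 (-0.80, SE 0.27, adjusted p = 1.0). SOX9, SOX6, ACAN, COL1A1 and COL1A2 had log2 changes of -0.30, -0.33, 0.14, -0.38 and -0.08 (adjusted p = 1.0 each). The sign of ACAN changed without donor 4 (-0.21) or its P6 library (-0.17), that of COL1A1 without the P6 library of donor 1 (0.02), and that of COL1A2 without donor 1 (0.02) and after quantile normalisation (0.01).

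Camera nevertheless placed 5 lists lower at P6 than at P3. These were cartilage matrix (median -0.54, 23 of 27 lower, adjusted p = 2.38e-05), fibrous matrix (-0.26, 20 of 28 lower, 0.00141), hypertrophy and mineralization (-0.19, 10 of 12 lower, 0.0129), cell cycle (-0.37, 32 of 35 lower, 7.17e-05) and ribosomal proteins (-0.13, 34 of 34 lower, 7.17e-05). With an estimated correlation these became adjusted p = 0.83 for the matrix lists and the hypertrophy list and adjusted p = 0.902 for the cell cycle and ribosomal lists. After quantile normalisation the fibrous matrix (0.166), hypertrophy (0.0734) and ribosomal (0.0734) calls ended, with no filter the hypertrophy call did (0.0803), and fry gave an adjusted p of 0.885 for each of the 5 lists. Over all genes 0 members of these lists passed, and adjusted over the list alone 1 hypertrophy gene fell. Median and camera differed in sign for the contractile, mesenchymal transition factor and synovial lists, which did not pass. The chondrogenic transcription factor list (adjusted p = 0.0503; 1 rose adjusted over the list alone) and the TGF-beta and BMP list (0.105) were lower only with the donor block (0.0158 and 0.0384, and adjusted p = 0.781 for both with the block and an estimated correlation). The other 22 lists did not pass with or without it. The ribosomal call ended without the P6 library of donor 3 (0.23) or 4 (0.608), and without donor 4 its adjusted p was 0.902, in the other direction. The cell cycle call ended without the P3 library of donor 1 (0.245), the P6 library of donor 3 (0.207) or donor 3 (0.388), and the hypertrophy call without the P3 library of donor 3 (0.066) or the P6 library of donor 1 (0.111).

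The early change was set against the late one directly. No gene passed this test (smallest adjusted p 0.167, 1107 genes unadjusted; 0 with the block, 1851 unadjusted; 0 with voom and 6 with voom and the block), so no gene was shown to change more in one interval than in the other. COL2A1 had the value -3.75 (SE 1.55, adjusted p = 0.775), SOX9 -1.88 (SE 0.52, adjusted p = 0.575) and COL1A1 2.24 (SE 0.92, adjusted p = 0.773). Camera placed 7 lists apart, cartilage matrix and chondrogenic transcription factors below 0 and fibrous matrix, contractile, NF-kB, mitochondrially encoded and ribosomal protein genes above 0. None of these held with an estimated correlation (smallest adjusted p = 0.289), and the mitochondrial list had the other sign after quantile normalisation (adjusted p = 0.944). Adjusted over the list alone 7 cartilage matrix genes and 1 hypertrophy gene passed, all below 0. The YAP, matrix proteinase, TGF-beta, WNT, antioxidant, cholesterol and adipocyte lists, which did not pass, had medians below 0 and a camera direction above.

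The changes from P0 to P3 and from P0 to P6 were correlated across genes (r = 0.84, across genes, which are not independent replicates). Both use the same P0 libraries, and unchanged groups simulated against shared controls gave r = 0.50 (20 simulations). With different P0 libraries for the 2 comparisons the mean r was 0.52, with a lowest value of 0.43, although the P3 and P6 libraries still came from the same donors. The covariance was 0.209, against 0.051 in the simulations, a difference of 0.158. The 2 comparisons shared 62 calls, 8 that rose and 54 that fell in both, among them COL2A1, SOX9, SOX5, FLNC and MSC. Independent lists would share 0.1 and 1.9, and the simulations shared 0. Both baselines are too low, since the 2 lists rest on the same P0 libraries and donors. The simulations drew every library and gene independently, without differences between donors.

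The makeup of the libraries was compared by shares of the summed TPM. Mitochondrially encoded protein genes held 9.07 ± 0.482% of the summed TPM at P0, 11.7 ± 1.36% at P3 and 12.4 ± 0.785% at P6, and the 10 most abundant genes held 12.1 ± 1.02%, 15.0 ± 1.08% and 16.1 ± 1.27%. In both measures every P3 and P6 library lay above every P0 library (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0857 over 12 tests), which does not pass after adjustment. The share of the 10 most abundant genes rose by 2.96 percentage points at P3 and 4.02 at P6. With mitochondrially encoded genes left out it rose by 1.57 and 2.11, so the 2 measures are not separate results. Between P6 and P3 the exact permutation adjusted p was 0.686 and 0.514. Ribosomal protein genes held 5.32 ± 0.894%, 6.03 ± 0.530% and 5.58 ± 1.39% (exact permutation adjusted p = 0.514 for P3, 0.842 for P6 against P0 and 0.720 for P6 against P3), and replication-dependent histones 0.043 ± 0.018%, 0.036 ± 0.011% and 0.041 ± 0.011% (0.720, 0.886 and 0.720).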

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

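Several tests below were chosen after the results were seen. These were the test of whether donors kept their differences along the first component, the test of scaling and the comparison within short RNA genes. So were the reading given to the test of the P0 axis and the counts over other splits of the libraries. The predictions of the other tests of causes were written before their values were seen. The spread of the P0 libraries and the pattern of short RNA and intron genes were not planned results, so all tests of their causes followed the patterns. The thinnings also rest on the recovered reads, a method chosen after the data were seen.

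The 4 P0 libraries lay far apart on the first principal component (SD 32.6, against 12.7 at P3 and 6.1 at P6). Depth is argued against, since the SD was 32.5 after all libraries were thinned to 23220000 estimated reads (5 thinnings, 32.4 to 32.5). A difference between donors kept at the same size along this component would leave a like spread at P6, where the SD was 6.1. That value is part of the pattern as flagged, so it is no separate test of this cause. Donor 1 had the lowest score at P0, P3 and P6 (-82.6, -2 and 16.9). These values speak only for the first component. On the second component donors 1 to 4 lay at 2.8, -0.1, -21.2 and -21.6 at P0 and at 63.5, 19.4, -28.2 and -28 at P6. Donor differences as such were therefore not shown to be lost. That the P0 cultures stood at different points of the change with passage stays open. The main axis among the P0 libraries correlated with the P6 minus P3 change at r = 0.06 across genes, which lay under the bound of 0.1 set beforehand against this explanation; without the short RNA and intron genes r was 0.11, and the P6 minus P3 change itself correlated at only 0.01 to 0.31 between sets of donors, so a low r decides little, a reading adopted after the value was seen.

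Genes for short RNAs and noncoding genes inside introns (1736 genes, 865 of them short RNA genes) were lower at P3 than at P0 and P6. Their median early minus late log2 change was -0.54, against -0.10 for the other genes tested. They held 0.832 ± 0.095% of the TPM at P0, 0.657 ± 0.058% at P3 and 0.757 ± 0.09% at P6, with P3 lowest in 4 of 4 donors. Of the estimated reads they held only 0.09 ± 0.01%, 0.08 ± 0.01% and 0.09 ± 0.01%, also with P3 lowest in 4 of 4 donors. Their mean log2(TPM + 1) was 1.65, 1.33 and 1.58. The pattern therefore rests on low levels and few reads per gene. Depth is argued against, with a median of -0.52 after thinning (-0.54 to -0.51). Scaling by abundant genes is argued against as the whole cause, since median-of-ratios rescaling moved the median of the other genes from -0.10 to 0.04 and left that of these genes at -0.45 (95% bootstrap interval over genes -0.49 to -0.4). The difference of -0.36 between noncoding genes inside introns and those outside protein-coding genes decides nothing about unspliced RNA, because the former belong to the pattern by definition. Among short RNA genes, which belong to it wherever they lie, the 576 inside introns had a median of -0.76 and the 257 outside protein-coding genes -0.48. The difference was -0.28 (95% bootstrap interval over genes -0.45 to -0.1). Both bootstrap intervals redraw genes, which vary together within a library, so they do not measure the spread over the 4 donors. The classes of short RNA inside and outside introns were not matched. Fewer reads from unspliced RNA in the P3 libraries may be part of the cause, but this is not shown, and the short RNA genes outside were low too. Whether a library batch followed passage, or the cells at P3 held less unspliced RNA, stays open, because the labels give no batch.

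For P3 against P0, 1 of 35 splits of the 8 libraries, the real one, called as many genes (70, highest other 2). For P6 against P0 it was also 1 of 35 (785, highest other 9). These splits leave the donor pairing aside, and a split that mixes passages puts the passage change into the spread within its groups. Low counts in the other splits therefore do not exclude chance. Among the 8 splits that part all 4 donor pairs, which are too few for a share under 0.05, the blocked fit gave 861 and 1885 in the real split and 0 in each other. For P6 against P3 and the early minus late change the real count was 0, which each of the 35 and of the 100 splits must reach, so these counts decide nothing (highest other 1 and 359). The 359 genes of 1 drawn split point to some structure of the samples, and which one was not tested.

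Camera placed 7 gene lists apart in the early minus late change, a test of the difference between the intervals itself. Cartilage matrix genes (adjusted p = 6.65e-08) and chondrogenic transcription factors (0.00651) lay below the other genes. Fibrous matrix (1.43e-08), contractile (3.28e-05), ribosomal protein (4.72e-10), NF-kB (0.0101) and mitochondrially encoded genes (0.00939) lay above them. With an estimated correlation the smallest adjusted p was 0.289. Fry gave 0.338 or above for all 7. The NF-kB value was 0.107 with a filter of 5 TPM, 0.115 after median-of-ratios rescaling, 0.152 after quantile normalisation, 0.17 without donor 1, 0.0624 without donor 4, 0.0826 without the P0 library and 0.158 without the P3 library of donor 1. The mitochondrial value was 0.944 with the other sign after quantile normalisation, 0.0508 without donor 1, 0.556 without donor 2, and 0.0758 and 0.355 without their P3 libraries. The transcription factor value was 0.0575 without the P3 library of donor 4.

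In 21 of 297 groups of 4 libraries tested, 1 library lay farther from the others than Dixon's 95% critical value allows, where chance gives 14.8. The first value given is its gap to the nearest library over the whole range. For genes this ratio was taken on the log2(TPM + 1) scale, whereas the levels beside it are in TPM. At P0 these were CNMD (0.886; 108 TPM against 21.1 to 25.5), COL9A2 (0.895; 217 against 28.2 to 35.1), FGFR3 (0.900; 98.9 against 23 to 26.7), LMOD1 (0.939; 1.48 against 12.8 to 14.4), all in donor 1, MFAP5 (0.833; 3.54 against 0.0945 to 0.388) and TGFB2 (0.923; 42.6 against 71.6 to 74.7). At P3 they were B3GNT7 (0.928; 0.556 against 1.33 to 1.41), CDKN1A (0.879; 520 against 817 to 870), COL14A1 (0.897; 217 against 298 to 310), MT-ND3 (0.938; 2440 against 3060 to 3110), NKX3-2 (0.915; 15.4 against 8.03 to 8.50), S100A4 (0.851; 1070 against 524 to 582), SOX8 (0.914; 1.39 against 8.60 to 9.93) and WNT11 (0.868; 1.70 against 0.826 to 0.923). At P6 they were B3GNT7 (0.958; 2.06 against 0.556 to 0.601), CNMD (0.856; 0.867 against 0.211 to 0.289), COL1A1 (0.862; 2600 against 7270 to 8570), GDF10 (0.912; 2.87 against 0.931 to 1.05), HIST3H2A (0.843; 28.6 against 9.84 to 11.7), LAPTM5 (0.845; 1.11 against 0.280 to 0.383) and MMP13 (0.840; 4.81 against 0.363 to 0.719).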

How the results depend on the processing

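Voom with and without the replicate block, and an estimated correlation with the block, were chosen after the data were seen; the other alternatives were planned. No named gene that passed its test changed sign under any alternative listed here, but many calls were lost. Of the named calls, 12 were lost after median-of-ratios rescaling and 9 after quantile normalisation. With no filter 42 were lost, and with only the passages compared 62. Those of ZEB1, PDIA6, CD55 and B3GAT3 for P6 against P0 were lost under each of these, and that of GLB1 after median-of-ratios rescaling. Of the named genes that did not pass, ACAN changed sign in all 3 comparisons of passages, and COL1A1 and COL1A2 did for P6 against P3. The ACAN log2 change for P3 against P0, -0.63, was 0.06 without the P0 library of donor 1. The genes called for P3 against P0, P6 against P0, P6 against P3 and early minus late were 70, 785, 0 and 0, and the lists called 11, 11, 5 and 7; the cause of a change was not tested unless given. With the donor as a replicate block 861 and 1885 genes passed for P3 and P6 against P0, and beside the calls named above the block changed no other call of a named gene or list. Voom with the block gave 1126, 2042, 4 and 6. With only the passages compared 14 and 253 passed, with fewer libraries behind the spread, and with no filter 23, 394 and, for P6 against P3, 1, with 40488 genes tested. For P6 against P3 and early minus late, pseudocount 0.1 gave 4 and 3 and no trend gave 1 and 1; without mitochondrially encoded genes P6 against P3 gave 1. An estimated correlation called 0 lists in all 4 comparisons, with and without the block; fry called 7 for P3 against P0, 10 for P6 against P0 and 0 for P6 against P3 and for early minus late. Of the lists called for P3 against P0, fry missed fibrous matrix, contractile, NF-kB, cell cycle, senescence, hypoxia and ribosomal genes, and of those for P6 against P0 contractile, cell cycle and senescence genes. It placed lower some lists that camera did not call. For P3 these were IGF and FGF (fry adjusted p = 0.0346), endoplasmic reticulum stress (0.047) and osteoblast markers (0.0285). For P6 they were antioxidant genes (0.0454) and osteoblast markers (0.0138). With the donor block fry called 3 lists for P3 against P0 and 14 for P6 against P0. Its calls of IGF and FGF (0.154), endoplasmic reticulum stress (0.0571), osteoblast (0.0689) and mitochondrially encoded genes (0.0689) for P3 were then lost. That of antioxidant genes for P6 (0.0969) was lost too. Contractile (0.0392), cell cycle (0.0492), TGF-beta (0.032), synovial (0.032) and leukocyte (0.0392) lists then passed for P6. Quantile normalisation called 2 for P6 against P3, cartilage matrix and cell cycle, and reversed the mitochondrially encoded list in early minus late (adjusted p = 0.944). Leaving out libraries or donors gave 1 to 229, 73 to 987, 0 to 1 and 0 to 3 genes, and 10 to 15, 10 to 14, 5 to 8 and 6 to 10 lists. The lowest counts, 1 and 73, were without donor 2, and the highest, 229 and 987, without the P0 library of donor 3. For P6 against P3, 1 gene passed without the P0 library of donor 1 or the P6 library of donor 2, and 8 lists without donor 2 or the P3 library of donor 2 or 4; for early minus late 3 passed without the P0 library of donor 1 and 1 without donor 2, the P3 library of donor 4 or the P6 library of donor 2. The ribosomal list reversed for P6 against P3 without replicate 4 (adjusted p = 0.902; 2.97e-12 to 0.902 over the left-out libraries and donors). With 1 donor left out the exact test of a share of TPM (3 libraries against 3) cannot pass, so only the sizes are given; the ribosomal share of P6 minus P0 ranged from -0.4, without donor 1, to 0.788 percentage points. Depth limits genes near 1 TPM, where protein-coding genes rest on a median of 20 to 38 reads and short RNA genes on fewer.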

Other observations

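The AP-1 and immediate early genes, which respond within minutes to handling or serum, differed among the P0 libraries. The mean log2(TPM + 1) of the list was 5.58 and 5.61 in donors 1 and 2 and 7.14 and 6.98 in donors 3 and 4 at P0, 5.73 to 6.06 at P3 and 5.80 to 6.22 at P6. FOS was at 256, 189, 1180 and 1090 TPM in donors 1 to 4 at P0, and NR4A1 at 5.35, 8.75, 122 and 95.7.

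The number of genes with at least 1 TPM was lower in each P3 library (16215 to 16450) than in any P0 library (17029 to 18480) or P6 library (16606 to 17382).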
